A study of Marchantia polymorpha and Arabidopsis thaliana and Oryza sativa Japonica Group with 116 samples.

How the data were processed

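The deposited material was 4 count tables, 1 for Arabidopsis, 2 for Marchantia and 1 for rice, with GEO labels that gave species, genotype, treatment, time and replicate. Values in the Arabidopsis table were expected counts per the deposited file, of which 1.35% were not whole numbers, and these were rounded to whole numbers before testing. Values in the other 3 tables were counts per the deposited files. The submitters' processing notes name STAR, TAIR10 and IRGSP-1.0, and versions are not given in the sources used here. The labels give RNA extracted with RNeasy kits and standard Illumina libraries. The tables held 32853 genes for Arabidopsis, 19755 entries for the Marchantia G-protein table, 19355 for the Marchantia WRKY table and 37852 for rice. Among Marchantia G-protein entries, 3012 locus identifiers stood on 2 lines, which were summed to leave 16743 loci. Of 116 libraries, 115 held counts: 44, 36, 18 and 17 in the order above. The column of xlg1,4 24 h replicate 3 in rice held no counts and was left out. Samples were grouped by the labels alone, into 43 groups.

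Median total counts were 29.7, 10.5, 19.75 and 17.0 M per library. No library was a copy of another. The nearest library by expression belonged to the same group in 43 of 44 Arabidopsis, 25 of 36 Marchantia G-protein, 0 of 18 Marchantia WRKY and 10 of 17 rice libraries. All Marchantia libraries expressed male-linked loci. The first and second principal components held 28.8% and 22.2% of the variance in Arabidopsis and 32.1% and 14.0% in rice.

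Each table was tested on its own with edgeR 4.0.16 in R 4.3.3, and no test was made between tables. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and quasi-likelihood F-tests were run on 1 model per table with a mean per group. Within each comparison p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. All adjusted p-values for genes are from edgeR. Differences between salt responses were tested at 2 h and 24 h together, which gives no single SE, and values quoted for 1 time with an SE come from a test of that time alone. Fold changes against a group with 0 counts are lower bounds from a floor of 3 counts over the group. The p-values measure only the spread between libraries, which may be technical. Comparisons, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined, except where a later choice is stated. Mutants of the same table shared their wild-type libraries.

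Genes were named by a fixed rule: the G-protein genes in every comparison, the 10 largest called rises and falls of at least 10 CPM in the higher group whose libraries did not overlap (chance gives 10% for 3 against 3), the 10 smallest p-values for differences between responses, and 2 to 4 members of each gene list with the smallest p-values. The seed storage genes followed in single libraries were chosen after their values were seen. Arabidopsis symbols and coordinates came from the TAIR10.1 annotation. For Marchantia and rice the files do not pair identifiers with names, so at most 2 identifiers that rose and 2 that fell are given per comparison.

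There were 15 gene lists for Arabidopsis (abscisic acid and osmotic, CBF/DREB, G-protein, jasmonate and wounding, salicylic acid and defence, unfolded protein response, auxin, cell wall growth, clock, flavonoid and phenylpropanoid, glucosinolate, heat and oxidative, ion transport, photosynthesis, root tissue), and 281 of 284 members were found in the table. They were tested with camera in limma 3.58.1, which compares a list with other genes at a preset correlation of 0.01, and again with a correlation estimated from the data. The fry test, which asks whether the genes of a list move on balance one way or in either direction without comparing them with other genes, was run beside it. Of 240 list tests camera called 87, of which 4 were also called with an estimated correlation, 69 by fry in 1 direction and 66 by fry in either direction. Called members are also counted with p-values adjusted over the list alone.

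The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no low-count filter, a replicate block in the model and a model of only the groups compared. Each library of the compared groups was also left out in turn. Alternatives chosen after the data were seen are named as such in the text on how results depend on processing. Where replicates number 2, the library left alone is assumed to vary like the other groups. The procedure was also tested on simulated data with 200 changed genes, 66 or 67 for each fold change. These were drawn only from genes over a minimum expression in the wild type at 0 h, so recovery of weaker genes was not measured. For salt responses the change was put into the mutant at 2 h only, so changes at 24 h were not simulated. For gpa1-3 against Col-0 at 0 h in Arabidopsis, with 19924 genes tested, the procedure recovered 53.7% of genes changed 1.5-fold, 86.6% changed 2-fold and 100.0% changed 4-fold. For gpa1-2 against Tak-1 at 0 h in Marchantia, with 9823 genes tested, it recovered 56.7%, 73.1% and 97.0%. For rice xlg1,4 against NB at 0 h it recovered 7.5%, 62.7% and 90.9%, and for the rice salt response 0.0%, 20.9% and 74.2%, with the spread of the libraries as labelled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, using numpy 2.4.6 and pandas 2.3.3.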

Results

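Messenger RNA was sequenced from wild-type plants and from mutants of heterotrimeric G-protein subunits or of WRKY transcription factors in the thale cress Arabidopsis thaliana, the liverwort Marchantia polymorpha and rice. Of 116 libraries in 43 groups, 115 held counts. Arabidopsis seedlings aged 7 days in liquid diluted MS medium under continuous light were sampled at 0 h and after 2 h and 24 h of 100 mM NaCl, with 3 libraries per group, and after 4 h of 0.3 µg/mL tunicamycin, a drug that blocks protein N-glycosylation in the endoplasmic reticulum, with 2 libraries per group. The genotypes were Col-0, gpa1-3 (canonical Gα subunit), agb1-2 (Gβ subunit) and the triple mutant xlg1,2,3 (extra-large Gα subunits). Marchantia gemmalings of the male wild type Tak-1 and of gpa1-2, gpb1-2 and xlg1-2 were sampled at 0, 2 and 24 h of NaCl in a table with 3 libraries per group. A separate Marchantia table held Tak-1, wrky6 and wrky12 at the same times with 2 libraries per group. Rice wild type NB and the mutant xlg1,4 were grown on plates in 16 h light and 8 h dark and sampled at the same times. By their labels there were 3 libraries per group and 2 for xlg1,4 at 24 h. Total counts per library were at least 14.1 M in Arabidopsis (median 29.7 M), 7.5 to 21.3 M in the Marchantia G-protein table, 18.1 to 26.6 M in the Marchantia WRKY table and 14.2 to 21.4 M in rice. In Arabidopsis, the libraries of replicate 3 (14.1 to 16.6 M) were shallower than those of replicate 1 (27.9 M or more) and replicate 2 (27.7 to 34.6 M). Values after ± are SD between libraries, expression is in CPM after TMM scaling, and the 0 h groups are the controls, as the time courses had no mock-treated group. Changes under NaCl or tunicamycin therefore cannot be told apart from those of elapsed time or handling.

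The genes targeted in each Arabidopsis mutant were examined before other genes. GPA1 (AT2G26300, TAIR10.1 chromosome 2, 11196996 to 11201102), the canonical Gα subunit, fell in gpa1-3 at 0 h from 119 ± 5.62 to 16.3 ± 0.925 CPM, a log2 change of -2.86 (SE 0.09, adjusted p = 2.6e-22). In xlg1,2,3 at 0 h, XLG2 (AT4G34390, chromosome 4, 16441086 to 16445017) fell from 95.2 ± 1.46 to 16.8 ± 3.68 CPM (log2 -2.50, SE 0.22, adjusted p = 2.8e-10) and XLG3 (AT1G31930, chromosome 1, 11464934 to 11469207) fell from 55.5 ± 4.29 to 12.3 ± 1.63 CPM (log2 -2.19, SE 0.11, adjusted p = 1.2e-16). XLG1 (AT2G23460, chromosome 2, 9995465 to 9999122) was higher in the same libraries, at 114 ± 5.74 against 68.5 ± 2.77 CPM (log2 0.73, SE 0.08, adjusted p = 8.5e-09). AGB1 (AT4G34460, chromosome 4, 16477031 to 16479620), the single Gβ gene, was at 139 ± 18 CPM in the libraries labelled agb1-2 and 130 ± 6.41 CPM in Col-0 at 0 h (log2 0.10, SE 0.11, adjusted p = 0.54). Its change under NaCl differed between agb1-2 and Col-0 at 2 h (log2 difference -1.10, SE 0.16, adjusted p = 6.5e-06) and at 24 h (-0.78, SE 0.16, adjusted p = 0.0005), to 57.8 against 116 CPM and 72.6 against 117 CPM. XLG3 was also lower in gpa1-3 at 0 h (log2 -0.60, SE 0.10, adjusted p = 6.2e-05), and GPA1 was lower in agb1-2 (log2 -0.32, SE 0.08, adjusted p = 0.0028). GPA1 was called lower in xlg1,2,3 at 0 h as well, and so in all 3 mutants.

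**Figure D1:**
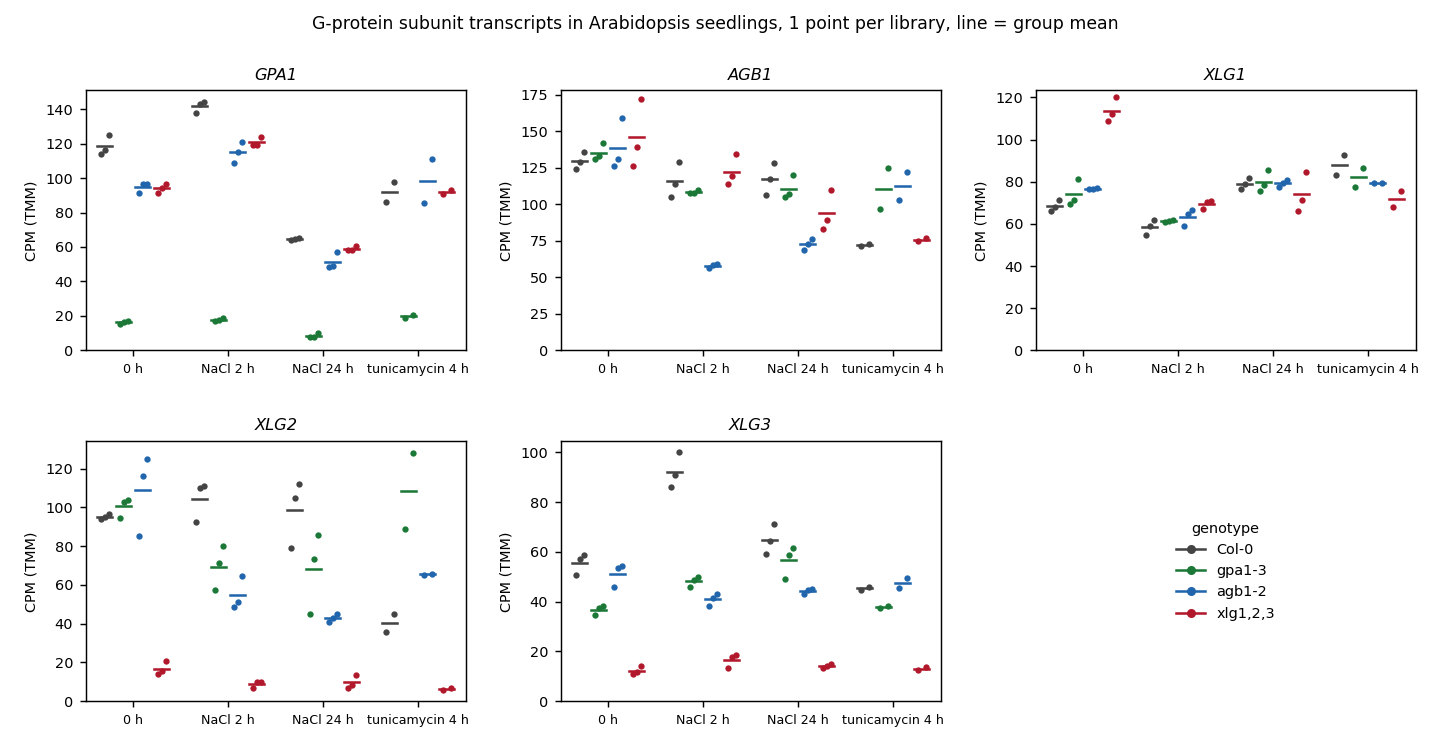
Expression of 5 G-protein subunit genes in CPM after TMM scaling (y axis, linear from 0) for each treatment (x axis) and genotype (colour), with 1 point per library and a line at the group mean. GPA1 lies at 16.3 CPM in gpa1-3 and 119 CPM in Col-0 at 0 h, XLG2 and XLG3 lie at 16.8 and 12.3 CPM in xlg1,2,3, and AGB1 in agb1-2 lies at 139 CPM at 0 h and 57.8 CPM at NaCl 2 h.

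The early salt response of the wild type was measured as Col-0 at NaCl 2 h against 0 h. Of the abscisic acid list, 23 of 30 members rose and 3 fell (23 and 3 adjusted over the list alone), with a camera adjusted p = 4.4e-10 (adjusted p = 0.1 with an estimated correlation). COR15A (AT2G42540), a cold- and drought-induced chloroplast protein, reached 12.5 ± 2.99 CPM from 0.109 ± 0.0415 (log2 6.68, SE 0.39, adjusted p = 5e-16), and P5CS1 (AT2G39800), which catalyses the committed step of proline synthesis, reached 512 ± 141 CPM from 23.3 ± 2.48 (log2 4.46, SE 0.19, adjusted p = 1.2e-19). RD22 (AT5G25610), a dehydration-induced gene, rose 32.8-fold. Wall genes fell: XTH16 (AT3G23730), a xyloglucan endotransglucosylase, dropped from 99.6 ± 2.96 to 0.869 ± 0.482 CPM (log2 -6.70, SE 0.27, adjusted p = 2.3e-20), and CESA6 (AT5G64740), a cellulose synthase of the primary wall, from 711 ± 24.2 to 119 ± 21.5 CPM (log2 -2.58, SE 0.10, adjusted p = 1.5e-20). ICS1 (AT1G74710), which makes the precursor of salicylic acid, rose 15.6-fold, and FRK1 (AT2G19190), a receptor kinase gene of the immune response, rose 14.5-fold to 774 ± 190 CPM (adjusted p = 8.7e-13). TT5 (AT3G55120), chalcone isomerase, rose 7.83-fold, and CHX17 (AT4G23700), a cation/proton exchanger, rose 12.2-fold. GH3.3 (AT2G23170), which conjugates auxin to amino acids, fell 87.7-fold, and NDL2 (AT5G11790), one of the proteins that bind Gβ, fell 11.5-fold (adjusted p = 6.6e-21). Of the cell wall list, 15 of 16 fell (15 adjusted over the list alone; adjusted p = 2.8e-10, and 0.00014 with an estimated correlation). In the flavonoid list 12 of 15 rose (13 adjusted over the list alone; adjusted p = 1e-05, and 0.035 with an estimated correlation). The lists of salicylic acid (7 rose, 2 fell of 14), ion transport (9 rose, 2 fell of 15), unfolded protein response (2 rose, 11 fell of 29), jasmonate (1 rose, 9 fell of 19), auxin (2 rose, 5 fell of 8), clock (9 rose, 3 fell of 15) and root tissue (5 rose, 1 fell of 13) had camera adjusted p of 0.076 to 0.1. The photosynthesis list had 5 rises and 4 falls among 26 members, and its median (-0.15), mean (0.01) and test direction (down, adjusted p = 0.74) differed in sign. Across 20858 genes tested, 11744 were called, with 5929 higher (2372 by at least 2-fold) and 5815 lower (2195 by at least 2-fold).

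After 24 h of NaCl the same comparison in Col-0 showed the later response. CBF2 (AT4G25470), a transcription factor of the cold response, rose from 1.53 ± 0.213 to 73.4 ± 25.6 CPM (log2 5.55, SE 0.60, adjusted p = 1.5e-09). NHX2 (AT3G05030), a vacuolar sodium and potassium/proton exchanger, rose 2.12-fold (log2 1.09, SE 0.12, adjusted p = 5.3e-09), VHP1 (AT1G15690), the vacuolar proton pyrophosphatase, 2.08-fold, and SOS1 (AT2G01980), the plasma membrane sodium/proton exchanger, 1.72-fold (log2 0.79, SE 0.13, adjusted p = 2.4e-06). XTH16 stayed low at 3.35 ± 0.561 CPM (log2 -4.90, SE 0.23, adjusted p = 4.2e-18). CSD2 (AT2G28190), a chloroplast copper/zinc superoxide dismutase, rose 3.13-fold (adjusted p = 9.3e-16). CYP79B2 (AT4G39950), which starts indole glucosinolate and camalexin synthesis from tryptophan, fell from 72.8 ± 11.6 to 19.3 ± 4.76 CPM (adjusted p = 2.5e-06). LHCB2.1 (AT2G05100), a light-harvesting protein, rose 2.39-fold, and ERD10 (AT1G20450), a dehydrin, fell from 689 ± 39 to 104 ± 8.75 CPM (log2 -2.73, SE 0.22, adjusted p = 2.3e-12). The cell wall list fell in 12 of 16 members (camera adjusted p = 2e-06, and 0.0033 with an estimated correlation). Further lists were called by camera and lost the call with an estimated correlation. These were CBF/DREB (7 of 7 rose; adjusted p = 0.0018, and 0.33 with an estimated correlation), auxin (6 of 8 fell; 0.0018 and 0.14), ion transport (11 of 15 rose; 0.0099 and 0.33), photosynthesis (14 rose and 2 fell of 26; 0.0099 and 0.67), clock (9 rose and 2 fell of 15; 0.017 and 0.34) and glucosinolate (6 of 8 fell; 0.017 and 0.34). The abscisic acid list was mixed, with 14 of 30 rising and 6 falling (14 and 7 adjusted over the list alone; adjusted p = 0.31), and the root tissue list had 4 rises and 3 falls among 13 (adjusted p = 0.48). In all, 12059 genes were called, 6049 higher (2158 by at least 2-fold) and 6010 lower (2442 by at least 2-fold), and with DESeq2 5810 were higher and 6009 lower.

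**Figure D2:**
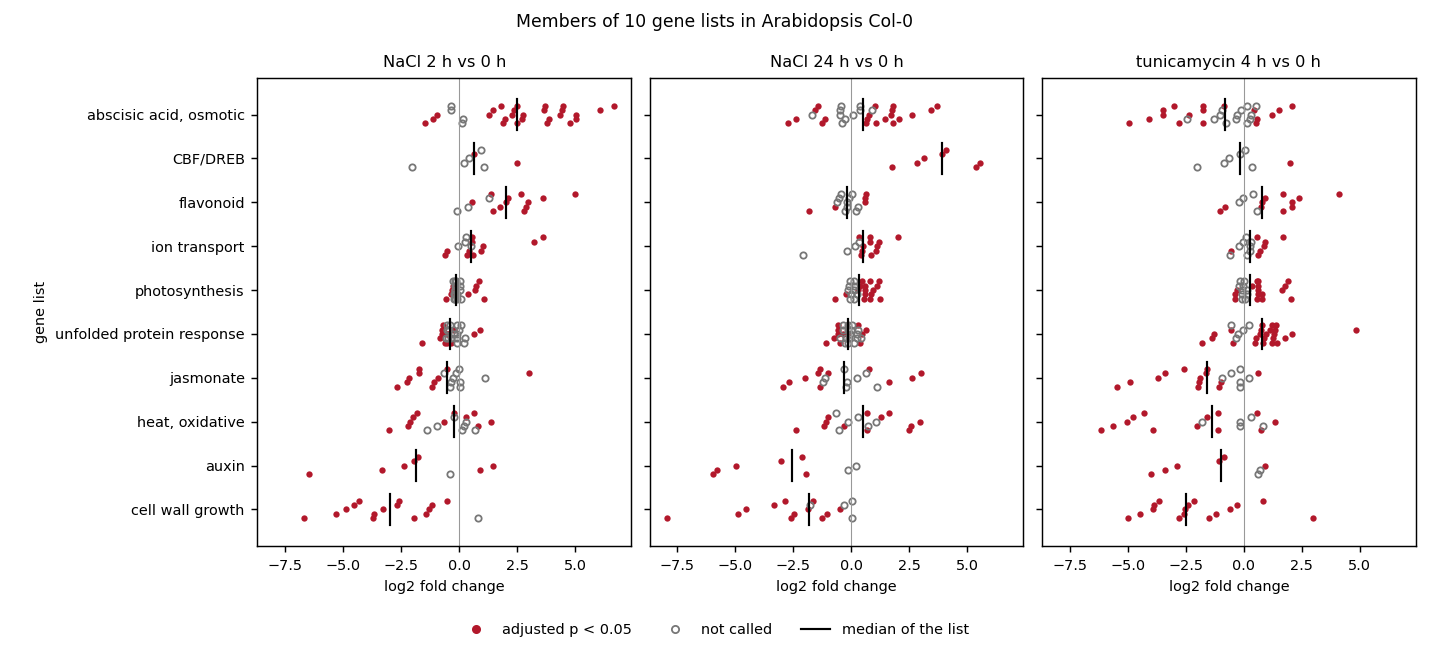
Log2 fold change (x axis) of each member of 10 gene lists (y axis) in Col-0 at NaCl 2 h, NaCl 24 h and tunicamycin 4 h against 0 h, with filled points for called genes, open points for others and a bar at the list's median. At NaCl 2 h 23 of 30 abscisic acid genes lie among the called rises and 15 of 16 cell wall genes among the called falls, and at NaCl 24 h 7 of 7 CBF/DREB genes rose.

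The gpa1-3 mutant was compared with Col-0 at 0 h to find differences present before treatment, with GPA1 itself lower by the log2 change of -2.86 given above. Among the genes that fell, CYP71A12 (AT2G30750), of the camalexin pathway, was at 1.34 ± 0.171 against 78.5 ± 14.6 CPM (log2 -5.90, SE 0.31, adjusted p = 9.8e-16), the chitinase CHIA (AT5G24090) at 1.59 ± 0.0344 against 28.1 ± 4.09 CPM, and FRK1 at 8.21 ± 0.52 against 53.3 ± 7.45 CPM (log2 -2.69, SE 0.31, adjusted p = 8.4e-08). RD22 was 4.48-fold higher (adjusted p = 6.3e-08) and RAB18 (AT5G66400), a dehydrin, 6.33-fold higher (adjusted p = 4.3e-05). LHCB3 (AT5G54270), a light-harvesting protein, was at 1320 ± 159 against 719 ± 112 CPM (log2 0.87, SE 0.10, adjusted p = 2e-07). The largest rises were seed storage genes: CRA1 (AT5G44120), a cruciferin, was at 77.7 ± 33.6 against 0.0917 ± 0.0827 CPM (log2 9.60, SE 2.84, adjusted p = 0.019) and CRU3 (AT4G28520), another cruciferin, at 65.5 ± 22.4 against 0.229 ± 0.0464 CPM. CRA1 also reached 10 CPM in 2 of 3 xlg1,2,3 libraries at 0 h (45.1 and 25.3 CPM) and at 2 h (64.1 and 31.7 CPM), whereas the 3 gpa1-3 libraries at 2 h were at 0.168 to 0.85 CPM. Photosynthesis genes were higher in 16 of 26 members (22 adjusted over the list alone; camera adjusted p = 4.7e-16, and adjusted p = 0.097 with an estimated correlation). Glucosinolate genes were lower in 6 of 8 (7 adjusted over the list alone; adjusted p = 3.7e-05, and 0.097 with an estimated correlation), and auxin genes higher in 5 of 8 (adjusted p = 0.0056, and 0.17 with an estimated correlation). Calls in the unfolded protein response list were 3 falls among 29 (8 adjusted over the list alone; adjusted p = 0.011, and 0.52 with an estimated correlation), and the root tissue list had 1 rise among 13 (adjusted p = 0.16). The salicylic acid and defence list had 1 member higher and 3 lower of 14 (2 and 5 adjusted over the list alone; adjusted p = 0.072). For heat and oxidative genes the median (-0.02) and mean (0.04) differed in sign (adjusted p = 0.47). Across the genome 2857 genes were called, 1272 higher and 1585 lower. Without Col-0 0 h replicate 2 the count was 1889.

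In the libraries labelled agb1-2 at 0 h, where AGB1 itself was not lower (adjusted p = 0.54), TT4 (AT5G13930), chalcone synthase, was at 12.9 ± 3.6 against 0.941 ± 0.313 CPM (log2 3.88, SE 0.30, adjusted p = 1.4e-11). CYP71A12 was at 0.263 ± 0.0885 against 78.5 ± 14.6 CPM (log2 -8.23, SE 0.38, adjusted p = 3e-17) and CHIA 31.8-fold lower. PAD3 (AT3G26830), of the last step of camalexin synthesis, was at 0.303 ± 0.204 against 6.36 ± 0.385 CPM (log2 -4.24, SE 0.35, adjusted p = 1.1e-10). PDIL2-3 (AT2G32920), a protein disulfide isomerase of the endoplasmic reticulum, was at 37.3 ± 2.29 against 64.8 ± 6.51 CPM (log2 -0.80, SE 0.15, adjusted p = 0.00016). PORC (AT1G03630), a protochlorophyllide reductase, was 2.16-fold higher (adjusted p = 6.4e-07), and EXPA10 (AT1G26770), an expansin, was at 28.4 ± 5.59 against 92.8 ± 7.95 CPM (adjusted p = 6.7e-07). The photosynthesis list was higher in 18 of 26 members (22 adjusted over the list alone; camera adjusted p = 5.6e-10, and 0.45 with an estimated correlation). Members of the unfolded protein response list were lower in 18 of 29 (19 adjusted over the list alone; adjusted p = 6.3e-05, and 0.74 with an estimated correlation). Glucosinolate genes were lower in 5 of 8 (adjusted p = 0.0038, and 0.45 with an estimated correlation). Abscisic acid genes were lower in 11 of 30 and higher in 2 (adjusted p = 0.01, and 0.81 with an estimated correlation). Root tissue genes went both ways (3 higher, 2 lower of 13; adjusted p = 0.27), as did flavonoid genes, whose median (-0.09) and mean (0.10) differed in sign (6 higher, 5 lower of 15; adjusted p = 0.68). Genes called numbered 6583, with 2887 higher and 3696 lower, and with only the compared groups fitted 3683 were higher and 3595 lower.

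In xlg1,2,3 at 0 h, 10 of 19 members of the jasmonate list were higher than in Col-0 (13 adjusted over the list alone; camera adjusted p = 1.1e-07, and 0.57 with an estimated correlation). LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, was at 46 ± 8.42 against 9.17 ± 1.14 CPM (log2 2.32, SE 0.22, adjusted p = 2.8e-09), and JAZ9 (AT1G70700), a repressor of jasmonate signalling, at 162 ± 28.6 against 55.9 ± 7.38 CPM (log2 1.53, SE 0.14, adjusted p = 6.7e-10). HEI10 (AT1G53490, chromosome 1, 19963267 to 19966952), a meiotic crossover factor, was at 29.4 ± 0.562 against 1.27 ± 0.523 CPM (log2 4.63, SE 0.16, adjusted p = 1.5e-20). RAB18 was 7.9-fold and ICS1 4.39-fold higher. CYP71A12 was at 0.222 ± 0.167 against 78.5 ± 14.6 CPM (log2 -8.58, SE 0.39, adjusted p = 1.7e-17), FRK1 8.89-fold lower, and SOS3 (AT5G24270), a calcium sensor of the sodium export pathway, at 9.8 ± 0.843 against 25.4 ± 3.39 CPM (adjusted p = 3.8e-09). The abscisic acid list had 8 of 30 higher (11 adjusted over the list alone; adjusted p = 0.003, and 0.58 with an estimated correlation), and the flavonoid list 6 of 15 higher (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.03, and 0.57 with an estimated correlation). No member of the unfolded protein response list was called by edgeR (adjusted p = 0.25), and 1 of 26 photosynthesis genes was higher (adjusted p = 0.25). Root tissue genes had 3 higher and 2 lower of 13 (4 and 2 adjusted over the list alone; adjusted p = 0.075). In total 3397 genes were called, 1624 higher and 1773 lower, and with DESeq2 1793 were higher and 1637 lower.

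The libraries of xlg1,2,3 and those labelled agb1-2 were also compared directly at 0 h. LOX2 was 8.73-fold higher in xlg1,2,3 (46 ± 8.42 against 5.22 ± 1.26 CPM, adjusted p = 1.9e-11), and CYP79B2 was at 70.1 ± 5.17 against 12 ± 2.1 CPM (log2 2.53, SE 0.31, adjusted p = 5.2e-07). RAP2.6 (AT1G43160), an ethylene response factor, was 5.41-fold higher and XLG2 6.46-fold lower. Abscisic acid genes were higher in 18 of 30 members (21 adjusted over the list alone; camera adjusted p = 1.2e-09, and 0.16 with an estimated correlation). Jasmonate genes were higher in 15 of 19 and lower in 1 (adjusted p = 1.8e-09, and 0.2 with an estimated correlation), and photosynthesis genes lower in 16 of 26 (18 adjusted over the list alone; adjusted p = 1.3e-09, and 0.2 with an estimated correlation). Unfolded protein response genes were higher in 9 of 29 (12 adjusted over the list alone; adjusted p = 0.00039, and 0.47 with an estimated correlation). In this comparison 4959 genes were called, 2790 higher and 2169 lower in xlg1,2,3.

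All 3 comparisons at 0 h used the same Col-0 libraries, so their overlap was set against simulated data with shared controls. The genes called in the same direction numbered 1871 for gpa1-3 and agb1-2, 1419 for gpa1-3 and xlg1,2,3, and 1839 for agb1-2 and xlg1,2,3, against 457, 234 and 539 for independent lists and at most 1, 0 and 0 in 20 simulations without differences. Without differences almost no gene is called, so the simulated counts cannot show how many shared calls come from the shared controls. Genes called in opposite directions numbered 51, 20 and 134. The covariance of the log2 changes across genes was 0.334, 0.382 and 0.365. It exceeded the simulated covariance by 0.276, 0.324 and 0.306, and part of the excess may come from the shared controls. Genes are not independent replicates.

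Whether gpa1-3 changed its salt response was tested as the difference between its changes and those of Col-0 at both times together. For every mutant such a difference also holds the difference from the wild type at 0 h, with the sign reversed. A difference at 0 h that faded can therefore also be called, and the 2 cases were not told apart. PYL4 (AT2G38310), an abscisic acid receptor, went from 168 ± 21.7 to 5.15 ± 1.47 CPM at 2 h in gpa1-3 and from 189 to 36.2 CPM in Col-0 (log2 difference -2.64 at 2 h and 0.41 at 24 h, adjusted p = 2.4e-07). NIT2 (AT3G44300), a nitrilase, rose more in gpa1-3 (differences 1.35 and 2.13, adjusted p = 2.3e-07). ICS1 rose less, by -3.81 (SE 0.44, adjusted p = 4.2e-06) at 2 h and -1.79 (SE 0.43, adjusted p = 0.0086) at 24 h, to 4.24 ± 0.682 CPM at 2 h against 40.9 CPM in Col-0. ABI2 (AT5G57050), a phosphatase that restrains abscisic acid signalling, rose more at 2 h (1.79, SE 0.26, adjusted p = 5e-05). Differences at 2 h were positive in 6 and negative in 1 of 30 abscisic acid genes (8 and 1 adjusted over the list alone; camera adjusted p = 4.1e-05, and 0.24 with an estimated correlation). They were negative in 4 of 15 flavonoid genes (7 adjusted over the list alone; adjusted p = 0.00026, and 0.14 with an estimated correlation) and in 4 of 8 glucosinolate genes (5 adjusted over the list alone; adjusted p = 0.00013, and 0.14 with an estimated correlation). At 24 h they were negative in 4 of 19 jasmonate genes (6 adjusted over the list alone; adjusted p = 1.5e-05, and 0.63 with an estimated correlation). Of the genes tested, 2361 were called, and the mutant's own changes correlated with those of Col-0 across genes at 0.81 (2 h) and 0.80 (24 h).

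The salt response of the libraries labelled agb1-2 differed from that of Col-0 in 6426 genes. HAI1 (AT5G59220), a phosphatase induced by abscisic acid, rose in agb1-2 from 3.95 ± 0.605 to 102 ± 13.3 CPM at 2 h and in Col-0 from 9.72 to 55.2 CPM (log2 difference 2.17, SE 0.29, adjusted p = 1.9e-06), with a difference of 0.13 (SE 0.30, adjusted p = 0.81) at 24 h. ICS1 stayed at 7.88 ± 1.73 CPM at 2 h against 40.9 CPM in Col-0 (-3.79, SE 0.42, adjusted p = 8.4e-08), and FRK1 reached 20.5 ± 4.48 against 774 CPM (-3.19, SE 0.41, adjusted p = 1.1e-06). At 24 h GH3.3 was at 112 CPM in agb1-2 and 2.16 CPM in Col-0 (6.26, SE 0.64, adjusted p = 5.8e-08), and EXPA10 at 44.8 against 12.6 CPM (3.54, SE 0.33, adjusted p = 1.4e-08). SUC1 (AT1G71880), a sucrose/proton symporter, had differences of -2.65 and -1.15 at the 2 times (adjusted p = 1.3e-08). The abscisic acid list had 15 of 30 positive differences at 2 h (22 adjusted over the list alone; camera adjusted p = 2.6e-13, and 0.11 with an estimated correlation). At 0 h camera had called this list lower in agb1-2 than in Col-0. The salicylic acid list had 5 of 14 negative differences at 2 h (7 adjusted over the list alone; adjusted p = 0.00014, and 0.2 with an estimated correlation) and 8 of 14 at 24 h (10 adjusted over the list alone; adjusted p = 0.00012, and 0.51 with an estimated correlation). Auxin genes had 6 of 8 positive differences at 24 h (adjusted p = 0.00013, and 0.083 with an estimated correlation). Root tissue genes had 3 of 13 negative differences at 2 h (adjusted p = 0.024, and 0.25 with an estimated correlation).

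For xlg1,2,3 the salt response differed from that of Col-0 in 2363 genes. AIG1 (AT1G33960), a gene induced by avirulent bacteria, went in xlg1,2,3 from 22.8 ± 2.86 CPM to 13.3 CPM at 24 h and in Col-0 from 5.05 to 31.8 CPM (differences -0.36 at 2 h and -3.44 at 24 h, adjusted p = 6.9e-10). ICS1, already higher in xlg1,2,3 than in Col-0 at 0 h, rose less, by -2.44 (SE 0.40, adjusted p = 0.00051) at 2 h and -3.41 (SE 0.41, adjusted p = 4.2e-06) at 24 h. Both differences include its higher level at 0 h. JAZ9 fell from 162 ± 28.6 to 52.9 ± 2.6 CPM at 2 h, against 55.9 to 39 CPM in Col-0 (-1.10, SE 0.20, adjusted p = 0.0013). CYP79B2 had a difference of -2.69 (SE 0.46, adjusted p = 0.0003) at 24 h. Jasmonate genes had 9 of 19 negative differences at 24 h (11 adjusted over the list alone; camera adjusted p = 2.5e-07, and 0.32 with an estimated correlation), and glucosinolate genes 5 of 8 (adjusted p = 3e-05, and 0.18 with an estimated correlation). At 0 h camera had called the jasmonate list higher in xlg1,2,3 than in Col-0. Of the abscisic acid list, 1 of 30 had a called positive difference at 2 h (4 and 1 negative adjusted over the list alone; adjusted p = 0.092). With only the compared groups fitted, 1088 genes were called.

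Tunicamycin was given to Col-0 for 4 h to stress the endoplasmic reticulum. The control was again 0 h, so effects of the drug and of elapsed time or handling are confounded. BIP3 (AT1G09080), a chaperone induced by unfolded proteins, rose from 6.9 ± 1.57 to 194 ± 41.6 CPM (log2 4.84, SE 0.49, adjusted p = 3.1e-10). UBC32 (AT3G17000), a ubiquitin-conjugating enzyme of the reticulum, rose 1.78-fold, whereas BAG7 (AT5G62390), a co-chaperone there, fell from 231 ± 13 to 66.2 ± 0.936 CPM (log2 -1.80, SE 0.12, adjusted p = 1.3e-14) and IRE1A (AT2G17520), a sensor of unfolded proteins, fell 2.58-fold (adjusted p = 6.8e-13). HSP70 (AT3G12580) fell from 987 ± 266 to 35.7 ± 4.5 CPM (log2 -4.79, SE 0.65, adjusted p = 1.7e-07), and ERD10 from 689 ± 39 to 22.2 ± 0.849 CPM (log2 -4.95, SE 0.30, adjusted p = 2.2e-15). JAZ10 (AT5G13220), a jasmonate repressor, fell 44.4-fold. RBCS2B (AT5G38420), a small subunit of Rubisco, rose 4.07-fold, and CESA6 fell 4.38-fold. Of the unfolded protein response list, 19 of 29 rose and 5 fell (19 and 5 adjusted over the list alone; camera adjusted p = 0.056). Cell wall genes fell in 14 of 16 and rose in 2 (adjusted p = 5.8e-06, and 0.005 with an estimated correlation), and jasmonate genes fell in 12 of 19 and rose in 1 (adjusted p = 0.0072, and 0.54 with an estimated correlation). Heat and oxidative genes had 3 rises and 10 falls of 18 (4 and 10 adjusted over the list alone; adjusted p = 0.054), the G-protein list 4 rises and 10 falls of 15 (adjusted p = 0.056), and root tissue genes 4 rises of 13 (adjusted p = 0.15). AGB1 itself fell 1.8-fold (log2 -0.85, SE 0.13, adjusted p = 9.1e-07). In total 11649 genes were called, 5890 higher and 5759 lower, and with DESeq2 5623 were higher and 5850 lower.

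The tunicamycin response of gpa1-3 was tested as its change minus that of Col-0. As for salt, this also holds the difference between the genotypes at 0 h, with the sign reversed. PYR1 (AT4G17870), an abscisic acid receptor, fell in gpa1-3 from 50.4 ± 0.851 to 11.8 ± 1.22 CPM and went from 51 to 41.8 CPM in Col-0 (log2 difference -1.80, SE 0.17, adjusted p = 4.9e-08), and PYL6 (AT2G40330), another receptor, had a difference of -3.73 (SE 0.38, adjusted p = 1.4e-07). BZIP60 (AT1G42990), a transcription factor of the unfolded protein response, went from 96.2 ± 9.55 to 255 ± 53.2 CPM in gpa1-3 and from 138 to 110 CPM in Col-0 (1.73, SE 0.34, adjusted p = 0.00053). NAC062 (AT3G49530), another factor of that response, had a difference of 1.86 (SE 0.39, adjusted p = 0.0013), and ERD10 one of 2.82 (SE 0.34, adjusted p = 1.8e-06). Unfolded protein response genes had 10 of 29 positive differences (19 adjusted over the list alone; camera adjusted p = 1.8e-07, and 0.24 with an estimated correlation), abscisic acid genes 15 of 30 (18 adjusted over the list alone; adjusted p = 1.3e-12, and 0.11 with an estimated correlation), and salicylic acid genes 8 of 14 (10 adjusted over the list alone; adjusted p = 1.3e-07, and 0.13 with an estimated correlation). CBF/DREB genes had 4 of 7 (5 adjusted over the list alone; adjusted p = 3.8e-05, and 0.16 with an estimated correlation). Photosynthesis genes had 18 of 26 negative differences (21 adjusted over the list alone; adjusted p = 4.6e-15, and 0.11 with an estimated correlation). At 0 h camera had called this list higher in gpa1-3 than in Col-0. Of 3309 genes called, the change was smaller in gpa1-3 than in Col-0 in 66.8%. The count was 1594 without Col-0 tunicamycin replicate 2 and 2093 without gpa1-3 tunicamycin replicate 2.

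The same test for the libraries labelled agb1-2 called 2376 genes, and the change was smaller than in Col-0 in 83.8% of them. TT4 fell in agb1-2 from 12.9 ± 3.6 to 3.37 ± 0.905 CPM and rose in Col-0 from 0.941 to 2.89 CPM (log2 difference -3.66, SE 0.45, adjusted p = 4.2e-05). HSP70 was at 436 ± 276 CPM after tunicamycin in agb1-2 and 35.7 CPM in Col-0 (3.84, SE 0.77, adjusted p = 0.0018). ERD10 fell less (2.25, SE 0.34, adjusted p = 0.00011), and PORC had a difference of -1.36 (SE 0.23, adjusted p = 0.00027). Photosynthesis genes had 11 of 26 negative differences (15 adjusted over the list alone; camera adjusted p = 3.5e-10, and 0.24 with an estimated correlation), and abscisic acid genes 8 of 30 positive (9 adjusted over the list alone; adjusted p = 1.3e-05, and 0.24 with an estimated correlation). Unfolded protein response genes had 4 of 29 positive (5 adjusted over the list alone; adjusted p = 5e-05, and 0.24 with an estimated correlation). At 0 h camera had called the photosynthesis list higher and the unfolded protein response and abscisic acid lists lower in agb1-2 than in Col-0. Heat and oxidative genes had 6 positive and 1 negative of 18 (9 and 2 adjusted over the list alone; adjusted p = 0.00082, and 0.24 with an estimated correlation), and root tissue genes 2 of 13 negative (3 adjusted over the list alone; adjusted p = 0.0082, and 0.24 with an estimated correlation). Without Col-0 tunicamycin replicate 2 the count was 680, and without agb1-2 tunicamycin replicate 1 it was 1068.

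For xlg1,2,3 the tunicamycin response differed from that of Col-0 in 1192 genes. PDIL2-3 went from 49.6 ± 5.16 to 327 ± 31.6 CPM in xlg1,2,3 and from 64.8 to 150 CPM in Col-0 (log2 difference 1.5, SE 0.24, adjusted p = 0.00027). Other genes of protein folding and degradation in the reticulum also rose more, among them DER1 (AT4G29330, 1.10, SE 0.19, adjusted p = 0.00057), PDIL1-1 (AT1G21750, 1.22, SE 0.25, adjusted p = 0.0032) and PDIL1-2 (AT1G77510, 1.57, SE 0.32, adjusted p = 0.0034). XLG1 had a difference of -1.03 (SE 0.12, adjusted p = 3.5e-06), JAZ9 one of -1.78 (SE 0.22, adjusted p = 7.4e-06), and CYP79B3 (AT2G22330), a homologue of CYP79B2, one of -1.94 (SE 0.26, adjusted p = 3.3e-05). The unfolded protein response list had 12 of 29 positive differences (20 adjusted over the list alone; camera adjusted p = 3.8e-14, and 0.1 with an estimated correlation), and glucosinolate genes had 5 of 8 negative (5 and 1 positive adjusted over the list alone; adjusted p = 3.5e-05, and 0.1 with an estimated correlation). The list itself rose in each mutant, in 22 of 29 members in gpa1-3, 21 in agb1-2 and 22 in xlg1,2,3, with 6, 4 and 6 falls and adjusted p of 2.4e-06, 5.6e-06 and 1.1e-06 (0.47, 0.53 and 0.33 with an estimated correlation). The change was smaller than in Col-0 in 66.8% of the called genes. The count was 352 without Col-0 tunicamycin replicate 2, 595 without xlg1,2,3 tunicamycin replicate 1 and 565 without xlg1,2,3 tunicamycin replicate 2.

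**Figure D3:**
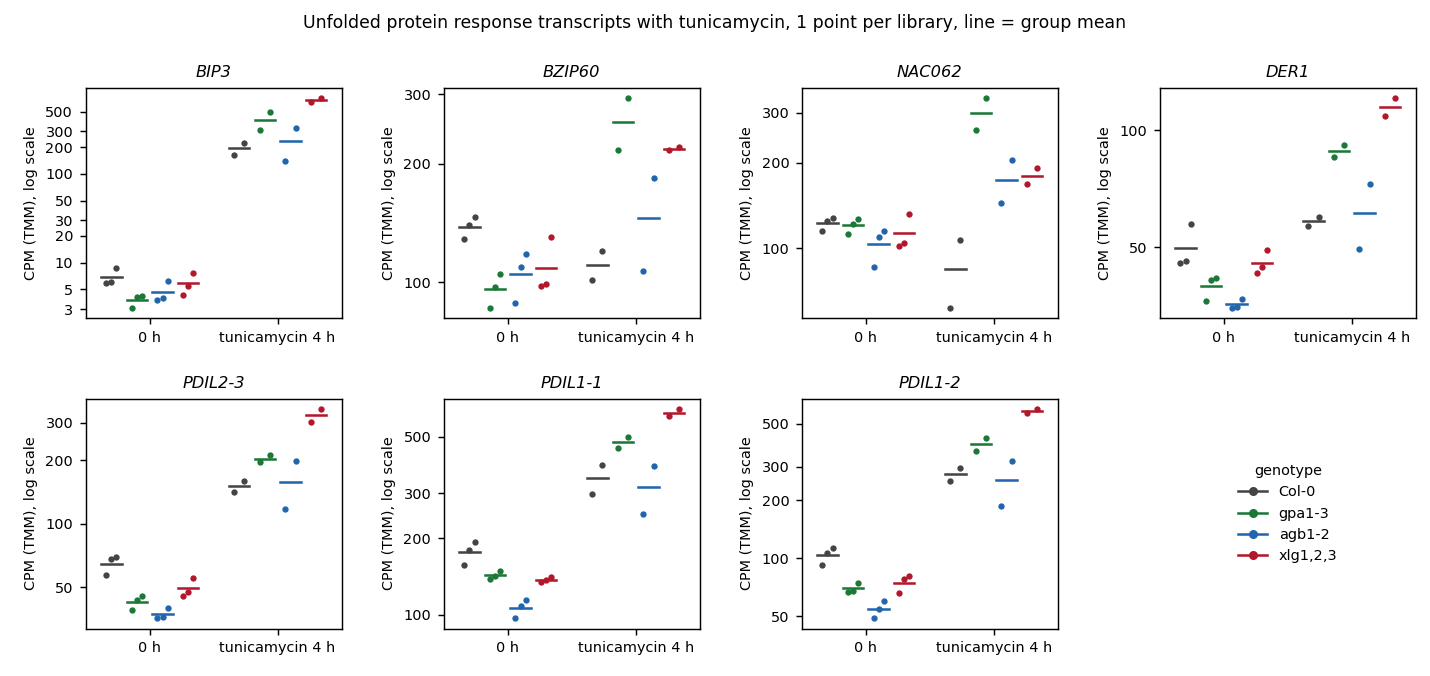
Expression of 7 unfolded protein response genes in CPM after TMM scaling (y axis, log scale) at 0 h and tunicamycin 4 h (x axis) for each genotype (colour), with 1 point per library and a line at the group mean. BIP3 rose from 6.9 to 194 CPM in Col-0, and PDIL2-3 reached 327 CPM in xlg1,2,3 against 150 CPM in Col-0.

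In the Marchantia G-protein table, the files do not pair locus identifiers with gene names, so identifiers are given. In Tak-1 at NaCl 2 h against 0 h, Mapoly0097s0034 rose from 0 counts to 74.9 ± 14.6 CPM, at least 743-fold (adjusted p = 1.6e-10), and Mapoly0037s0118 fell from 17.8 to 1.65 CPM (log2 -3.43, SE 0.34). Of 10296 genes tested, 2870 were called, 1525 higher and 1345 lower, and 1769 with only the compared groups fitted. At 24 h Mapoly0080s0040 rose from 0.273 to 104 ± 7.69 CPM (log2 8.53, SE 0.49), Mapoly0085s0007 fell from 34.4 to 0.303 CPM (log2 -6.74, SE 0.60), and 5569 genes were called, 2936 higher and 2633 lower (2310 and 2385 with only the compared groups fitted).

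Among the Marchantia mutants at 0 h, gpa1-2 had 127 called genes, 45 higher and 82 lower than Tak-1, and with only the compared groups fitted 75, 37 higher and 38 lower. Mapoly0001s0008 rose from 0 counts to 36.8 ± 6.02 CPM, at least 365-fold (adjusted p = 7.5e-13), and MapolyY_A0047 fell from 15.8 CPM to 0 counts, at least 149-fold (adjusted p = 2.4e-16). The gpb1-2 mutant had 361 called genes, 239 higher and 122 lower, and the count was 240 without Tak-1 0 h replicate 1 and 565 with a replicate block. Mapoly0005s0283 was at 14.1 against 0.238 CPM (log2 5.85, SE 0.37, adjusted p = 6.8e-10), and Mapoly0006s0125 at 14.1 against 115 CPM (log2 -3.02, SE 0.55). In xlg1-2, 139 genes were called, 75 higher and 64 lower, with 416 by DESeq2, 725 with a replicate block and 27 with only the compared groups fitted. Mapoly0016s0178 was at 721 against 263 CPM (log2 1.46, SE 0.14, adjusted p = 8.5e-08), and Mapoly0093s0018 had a log2 change of -2.03 (SE 0.19). The xlg1-2 count was 53, 237 and 49 without Tak-1 0 h replicate 1, 2 or 3, and 84 and 28 without xlg1-2 0 h replicate 1 or 2. Against gpb1-2, xlg1-2 had 107 called genes, 29 higher and 78 lower, with 172 by DESeq2 and 189 with a replicate block. With only the compared groups fitted 42 were called, 22 higher and 20 lower, and without the xlg1-2 libraries of replicate 1, an alternative chosen after the values were seen, 235. The highest and lowest changes among the named ones were Mapoly0027s0168 (log2 2.12, SE 0.45) and Mapoly0063s0004 (log2 -2.71, SE 0.52). That count was 70 and 23 without gpb1-2 0 h replicate 1 or 3, and 17 and 20 without xlg1-2 0 h replicate 2 or 3. The libraries of xlg1-2 replicate 1 lay between those of xlg1-2 and gpb1-2 at all 3 times. Genes called in the same direction numbered 43 for gpb1-2 and xlg1-2, 18 for gpa1-2 and gpb1-2, and 14 for gpa1-2 and xlg1-2, against 2, 2 and 1 for independent lists. All 3 shared the Tak-1 libraries at 0 h. The correlations across genes were 0.69, 0.21 and 0.30, against 0.53, 0.51 and 0.51 in simulations without differences, and the covariance exceeded the simulated one by 0.122, 0.017 and 0.024. Part of any excess may come from the shared controls. Replicate 3 of gpb1-2 and xlg1-2 had 19.0 to 21.3 M counts and that of Tak-1 and gpa1-2 10.2 to 11.5 M. Libraries of the same replicate number deviated together at 0 h in 3 of 3 pairs of Tak-1 with gpa1-2 and of gpb1-2 with xlg1-2, and in 0 of 3 pairs of Tak-1 with gpb1-2 or with xlg1-2. Differences of gpb1-2 and xlg1-2 from Tak-1, and the genes they shared, are therefore confounded with these 2 sets of libraries.

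The salt responses of the Marchantia mutants were tested against Tak-1 at both times together. For gpb1-2, 262 genes were called, and the change at 24 h was smaller than in Tak-1 in 77.5% of them, whereas at 2 h it was smaller in 45.4%. Mapoly0022s0142 had log2 differences of 0.14 at 2 h and -2.79 at 24 h (adjusted p = 1.9e-06), and Mapoly0049s0007 of 0.02 and -1.56 (adjusted p = 5e-06). The gpb1-2 count was 121 and 91 without gpb1-2 24 h replicate 2 or 3, and 105 without Tak-1 24 h replicate 1 or without replicate 2, and it was 535 with DESeq2 and 452 with a replicate block. For gpa1-2, 6 genes were called (685 at an unadjusted p under 0.05 where chance gives 515, 48 by DESeq2 and 11 with a replicate block), among them Mapoly0023s0017 with differences of 0.44 and 1.63 (adjusted p = 2.3e-09). The gpa1-2 count was 2 without gpa1-2 24 h replicate 2. For xlg1-2, 1 gene was called, Mapoly0049s0007 with differences of 0.00 and -1.16 (adjusted p = 0.0046), beside 701 genes at an unadjusted p under 0.05 where chance gives 515, 56 by DESeq2, 21 with a replicate block and 0 with only the compared groups fitted or without the xlg1-2 libraries of replicate 1. The xlg1-2 count was 2 without Tak-1 0 h replicate 1 or 3, Tak-1 24 h replicate 3, xlg1-2 0 h replicate 3, xlg1-2 2 h replicate 2 or xlg1-2 24 h replicate 1, 3 and 6 without Tak-1 2 h replicate 3 and 2, 4 without xlg1-2 24 h replicate 2 and 10 without xlg1-2 2 h replicate 1. In simulated data for the gpa1-2 salt response, with changes at 2 h only, 22.4% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 86.4% of those changed 4-fold were recovered.

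In the Marchantia WRKY table, Tak-1 was again compared between times. At NaCl 2 h Mp6g06100 rose from 0.425 to 194 CPM (log2 8.85, SE 0.71), Mp5g03920 fell (log2 -3.92, SE 0.38), and 3820 of 13225 genes were called, 1961 higher and 1859 lower (2042 and 2133 with DESeq2). The 2 h count was 2217 without Tak-1 0 h replicate 2, 2371 without Tak-1 2 h replicate 1 and 2084 without Tak-1 2 h replicate 2. At 24 h Mp5g12340 rose from 0 counts to 18.4 CPM, at least 223-fold, Mp2g25340 fell from 67.4 to 0.124 CPM (log2 -9.03, SE 0.58), and 5117 genes were called, 2556 higher and 2561 lower (2663 and 2613 with DESeq2). The 24 h count was 3322 without Tak-1 0 h replicate 2. Mp7g01940 was higher in both mutants at 0 h, at 4950 ± 202 CPM in wrky6 (log2 3.18, SE 0.12, adjusted p = 9.8e-09) and 12100 ± 76.3 CPM in wrky12 (log2 4.46, SE 0.12, adjusted p = 2.6e-10), against 547 ± 70.5 CPM in Tak-1. In wrky6 8 genes were called and in wrky12 8, and 2 were shared. With only the compared groups fitted 0 and 3 were called, with Mp7g01940 at an adjusted p = 0.11 in wrky6 and 0.0021 in wrky12. DESeq2 called 22 and 181, and with no low-count filter 15 and 34 were called. Of the 18 libraries, 0 had their nearest library in their own group, and at 0 h libraries of the same replicate number deviated apart between Tak-1 and wrky6 (correlation -0.49) and wrky12 (-0.22). A replicate block with the Tak-1 0 h numbers crossed, chosen after the values were seen, gave 16 and 97 genes. The wrky6 count was 64 without wrky6 0 h replicate 1, and the wrky12 count was 1 or 2 with any of its 4 libraries left out. No gene was called by edgeR for the salt responses of wrky6 and wrky12, and 384 and 441 had an unadjusted p under 0.05, fewer than the 661 that chance gives. DESeq2 called 5 and 8, and with only the compared groups fitted 2 were called for wrky12. The wrky6 salt count was 2 without wrky6 0 h replicate 1. In simulated data for the wrky6 salt response, with changes at 2 h only, edgeR recovered 1.5% of genes changed 1.5-fold, 40.3% changed 2-fold and 83.3% changed 4-fold. DESeq2 recovered 7.5%, 55.2% and 89.4%. Genes called there without a simulated change numbered 31 by DESeq2 and 4 by edgeR, and for wrky6 at 0 h 15 and 0.

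In rice, NB at NaCl 2 h against 0 h had 24 called genes of 25482, 9 higher and 15 lower, against 1276 with only the compared groups fitted, 597 by DESeq2, 11 with DESeq2 size factors and 0 with a replicate block. Os05g0468800 rose from 0.909 to 10.4 CPM (log2 3.49, SE 0.61, adjusted p = 0.048), and Os02g0562600 fell (log2 -1.56, SE 0.28). At 24 h 5 genes were called, among them Os10g0345100 (log2 0.85, SE 0.12), Os12g0257500 (0.75, SE 0.12), Os02g0582900 (-3.13, SE 0.48) and Os06g0301400 (-1.32, SE 0.19), each at an adjusted p = 0.041. The 24 h count was 486 by DESeq2, 8 with no low-count filter, and 0 with only the compared groups fitted or with a replicate block. In xlg1,4 at 0 h against NB, 18 genes were called, 8 higher and 10 lower, against 127 with only the compared groups fitted (91 higher, 36 lower), 346 by DESeq2 (195 higher, 151 lower) and 12 with a replicate block (6 higher, 6 lower). Os12g0113600 was at 22.3 against 1.58 CPM (log2 3.81, SE 0.57, adjusted p = 0.021), and Os12g0178000 had a log2 change of -1.74 (SE 0.20, adjusted p = 0.0023). No gene was called by edgeR for the salt response of xlg1,4, and 4 by DESeq2, and 1353 had an unadjusted p under 0.05 where chance gives 1274. The library labelled NB 24 h replicate 3 lay with xlg1,4 on 100 genes that part the genotypes, at a score of 0.96 where the other NB libraries lay between -0.05 and 0.18. The libraries labelled xlg1,4 0 h replicate 3 and xlg1,4 2 h replicate 3 lay with the next time, at 1.18 and 0.97 on scales from 0 to 1. Without these 3 libraries, 1482 genes were called in NB at 2 h, 5214 in NB at 24 h, 681 in xlg1,4 at 0 h and 0 for the salt response. This alternative was chosen after the values were seen. Without NB 24 h replicate 3 alone, 2674 genes were called in NB at 24 h. With any 1 of the 6 libraries compared left out, the NB count at 2 h was 0. With any compared library other than NB 24 h replicate 3 left out, the NB count at 24 h was 0 or 1. With any 1 of the 6 libraries compared left out, the xlg1,4 count at 0 h was 2 to 8. Libraries outside each comparison were not left out singly.

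**Figure D4:**
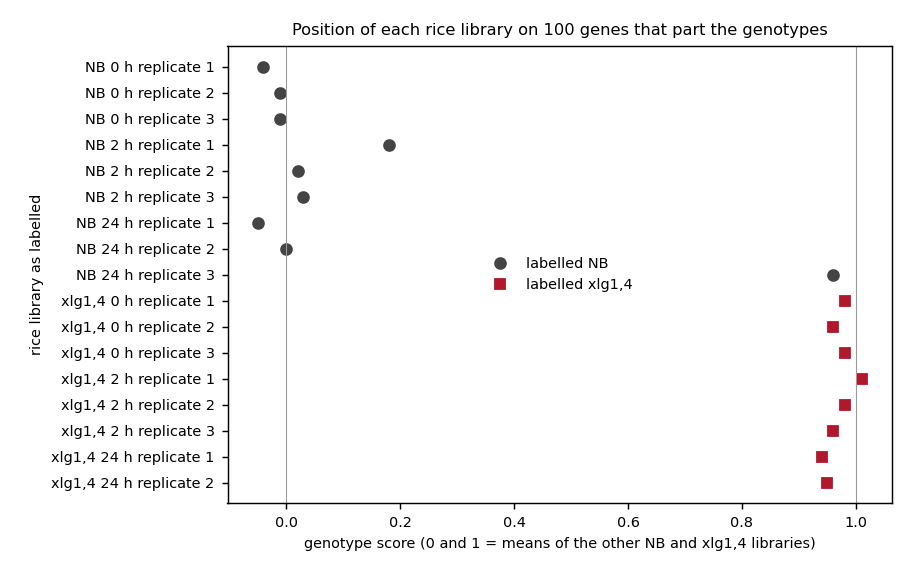
Position of each rice library (y axis, named as labelled) on the mean of 100 genes that part the genotypes, scaled so that 0 and 1 are the means of the other NB and xlg1,4 libraries (x axis, no unit). The library labelled NB 24 h replicate 3 lies at 0.96, among the xlg1,4 libraries (0.94 to 1.01).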

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

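The tests of the shared shift in Arabidopsis, of the rice libraries and of batches in Marchantia were chosen only after the results were seen, and the splits of the libraries were planned. The prediction for gpb1-2 material was written before its score was seen, but for a pattern already seen in the data.

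The following results drew attention because a mutant's response differed from that of the wild type in a direct test. Each such difference also holds the difference between the genotypes at 0 h, with the sign reversed. In Arabidopsis these were the salt responses of agb1-2 (6426 genes), gpa1-3 (2361) and xlg1,2,3 (2363). Also in Arabidopsis were the tunicamycin responses of gpa1-3 (3309 genes), agb1-2 (2376) and xlg1,2,3 (1192), with 2 tunicamycin libraries per genotype. Without Col-0 tunicamycin replicate 2 these 3 counts were 1594, 680 and 352. In Marchantia the salt responses of gpb1-2 (262 genes), gpa1-2 (6) and xlg1-2 (1) differed.

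Other splits of the same libraries were fitted with only the groups compared. For the salt responses 100 splits were drawn. The share of splits as large, the real one included, was under 0.05 for gpa1-3 (1 of 100 splits, 1661 genes and 1143 in the highest other split) and agb1-2 (2, 5953 and 5998). It was also under 0.05 for xlg1,2,3 (3, 1088 and 3163) and gpb1-2 (3, 201 and 769), but not for gpa1-2 (11, 6 and 234). These shares do not exclude chance, as the splits did not hold a constant difference between genotypes or the replicate numbers fixed. For xlg1-2 the fit of only the groups compared called 0 genes, so all 100 splits were as large by construction (44 in the highest) and the count says nothing of chance. Splits that called several times the real count, as for xlg1,2,3, gpb1-2 and gpa1-2, point to a structure of the samples. This may be the difference between genotypes itself, since regroupings within each time can exchange genotypes at 1 time only and so turn a constant difference into a response. For the gpa1-2 salt response the splits also ignored that 43 of 45 pairs of the same replicate number correlated over 0.1, and a replicate block called 11 genes.

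For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real value and the highest other split were 10173 and 0 for Col-0 at 2 h, 11501 and 0 for Col-0 at 24 h, 3838 and 0 for gpa1-3, 7278 and 0 for agb1-2, 3279 and 0 for xlg1,2,3, and 4594 and 0 for xlg1,2,3 against agb1-2. They were 1769 and 0 for Tak-1 at 2 h, 4695 and 0 at 24 h, 75 and 141 for gpa1-2, 247 and 0 for gpb1-2, 27 and 1 for xlg1-2, and 42 and 1 for xlg1-2 against gpb1-2. In rice they were 1276 and 0 for NB at 2 h, 0 and 0 for NB at 24 h, and 127 and 0 for xlg1,4. The number of splits as large, the real one included, was 2 for gpa1-2, 10 for NB at 24 h, where a real count of 0 makes it so by construction, and 1 for each other. The split that called 141 genes set Tak-1 replicates 1 and 2 with gpa1-2 replicate 1. In that comparison the replicate numbers paired the libraries (3 of 3 pairs over 0.1, lowest 0.33), this split parted 1 pair, and the 3 other splits that part all 3 pairs called at most 0 genes. With a replicate block 155 genes were called. Splits of the salt responses were drawn within each time without regard to replicate numbers.

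In rice, 3 libraries lay with another group than the one on their label. The library labelled NB 24 h replicate 3 had a genotype score of 0.96, and those labelled xlg1,4 0 h and 2 h replicate 3 had time scores of 1.18 and 0.97. With names displaced by 1 place, 16 of 17 libraries had their nearest library in their own group, against 10 as named. Column names displaced by 1 place from NB 24 h replicate 3 onward are therefore a candidate explanation (lowest of the 3 scores 0.96). The column of xlg1,4 24 h replicate 3, the last rice label, held no counts, which such a displacement would also leave. In that case the library without counts would be NB 24 h replicate 3. A swap of NB 24 h replicate 3 with xlg1,4 0 h replicate 3 was excluded, as the latter scored 0.98 on genotype. Lower depth of NB 24 h replicate 3 was excluded, as it had 16.5 M counts and the shallowest of the libraries not in doubt, with a genotype score of -0.05, 15.1 M. For xlg1,4 0 h and 2 h replicate 3 lower depth was not excluded, as the larger of them had 14.9 M counts, though xlg1,4 2 h replicate 2, with 15.3 M, scored 0.01 on the scale from 2 h to 24 h where the library labelled 2 h replicate 3 scored 0.97. Labels were kept in the results, and no biological explanation was tested.

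In Marchantia, xlg1-2 replicate 1 lay towards gpb1-2 on a scale from 0 (xlg1-2) to 1 (gpb1-2), at 0.36 at 0 h, 0.67 at 2 h and 0.55 at 24 h, where other xlg1-2 libraries lay at -0.34 to 0.25 and gpb1-2 at 0.87 to 1.14. That these libraries hold some gpb1-2 material may explain it (median 0.55), but the median passed the set bound of 0.5 narrowly and the 0 h library lay under it. A batch shared by all replicate 1 libraries was excluded, as the mean correlation with Tak-1 and gpa1-2 replicate 1 was -0.02. A batch shared by gpb1-2 and xlg1-2 only stays open, as their replicate 1 libraries had a mean correlation of 0.34 and all 3 pairs at 0 h were over 0.1. No biological explanation was tested.

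The 3 Arabidopsis mutants shared a shift from Col-0 at 0 h, with 1019 genes called in the same direction in all 3 (330 higher, 689 lower, against 38 for independent lists). Chance values of the shared Col-0 libraries were excluded as the whole cause, as 82.3% of these genes kept their direction at 24 h against other Col-0 libraries. A state of Col-0 at 0 h only was excluded as the whole cause. The median difference was 65.2% of that at 0 h at 2 h, 45.9% at 24 h and 33.6% after tunicamycin. The part lost may be particular to 0 h, or may come from choosing the genes by their 0 h values. A smaller share of root stays open: the highest of the 3 root list medians was 0.85 (the others 0.30 and 0.36), but members went both ways and 1 of 13 reached 10 CPM in Col-0 at 0 h. Photosynthesis genes were higher in gpa1-3 and agb1-2, by camera calls lost with an estimated correlation (adjusted p = 0.097 and 0.45). In xlg1,2,3 camera did not call the photosynthesis list. A common effect of G-protein loss may contribute but was not tested, and AGB1 itself was not lower in the libraries labelled agb1-2 at 0 h. A growth or batch difference of the Col-0 plants at all times stays open, as no label separates it from genotype.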

How the results depend on the processing

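The alternatives without the 3 rice libraries in doubt, without the 3 xlg1-2 libraries of replicate 1, with crossed replicate numbers and with repeated Marchantia identifiers kept apart were chosen only after the data were seen. Of 32 counts of called genes, those within 1.5 times the reported count numbered 19 with DESeq2 (13 higher), 31 with DESeq2 size factors in edgeR (1 lower), 29 with no low-count filter (3 higher), 20 with only the groups compared (3 higher, 9 lower) and 24 with a replicate block (6 higher, 2 lower). With repeated identifiers kept apart, 9 of 9 were. Of 292 called changes of genes named here, 57 were lost under at least 1 alternative (215 values with a library left out and 39 with other settings), and 0 turned to a call in the opposite direction. The balance of higher and lower genes was less stable: which was the larger number turned in 18 of 32 results, in 31 counts over 15 results with other settings and in 29 counts over 12 results with a library left out. For agb1-2 at 0 h it went from 2887 higher and 3696 lower to 3683 and 3595 with only the groups compared, and for xlg1,2,3 at 0 h from 1624 and 1773 to 1793 and 1637 with DESeq2. The cause was not tested.

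The counts outside that range were as follows, and the cause was not tested. With DESeq2 they were 48, 535 and 56 for the salt responses of gpa1-2, gpb1-2 and xlg1-2, 172 for xlg1-2 against gpb1-2, 416 for xlg1-2, 8 and 5 for the salt responses of wrky12 and wrky6, 181 for wrky12, 22 for wrky6, 597 and 486 for NB at 2 h and 24 h, 4 for the xlg1,4 salt response and 346 for xlg1,4. DESeq2 size factors in edgeR gave 11 for NB at 2 h. With no low-count filter they were 34 for wrky12, 15 for wrky6 and 8 for NB at 24 h. With only the groups compared they were 1088 for the xlg1,2,3 salt response, 1769 for Tak-1 at 2 h, 75 for gpa1-2, 0 for the xlg1-2 salt response, 42 for xlg1-2 against gpb1-2, 27 for xlg1-2, 2 for the wrky12 salt response, 3 for wrky12, 0 for wrky6, 1276 and 0 for NB at 2 h and 24 h, and 127 for xlg1,4. With a replicate block they were 11, 452 and 21 for the salt responses of gpa1-2, gpb1-2 and xlg1-2, 565 for gpb1-2, 189 for xlg1-2 against gpb1-2, 725 for xlg1-2, and 0 and 0 for NB at 2 h and 24 h. With the replicate block and Tak-1 0 h numbers crossed they were 97 for wrky12 and 16 for wrky6. Without the 3 xlg1-2 libraries of replicate 1 they were 0 for the salt response and 235 against gpb1-2. Without the 3 rice libraries in doubt they were 1482 and 5214 for NB at 2 h and 24 h, and 681 for xlg1,4.

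With each library of the compared groups left out in turn, all counts stayed within 1.5 times for 14 of 32 results. Libraries outside a comparison were not left out singly. A library left alone in its group is assumed to vary like the other groups. The lowest and highest counts were 1889 and 2384 for gpa1-3 (1889 without Col-0 0 h replicate 2). For tunicamycin responses they were 680 and 2341 for agb1-2 (680 without Col-0 tunicamycin replicate 2, 1068 without agb1-2 replicate 1), 1594 and 3071 for gpa1-3 (1594 without Col-0 replicate 2, 2093 without gpa1-3 replicate 2) and 352 and 1283 for xlg1,2,3 (352 without Col-0 replicate 2, 595 and 565 without xlg1,2,3 replicate 1 and 2). In the Marchantia G-protein table they were 2 and 8 for the gpa1-2 salt response (2 without gpa1-2 24 h replicate 2), 91 and 380 for that of gpb1-2 (121 and 91 without gpb1-2 24 h replicate 2 and 3, 105 without Tak-1 24 h replicate 1 or 2), 1 and 10 for that of xlg1-2 (2 without Tak-1 0 h replicate 1 or 3, Tak-1 24 h replicate 3, xlg1-2 0 h replicate 3, xlg1-2 2 h replicate 2 or xlg1-2 24 h replicate 1, 3 and 6 without Tak-1 2 h replicate 3 and 2, 4 without xlg1-2 24 h replicate 2 and 10 without xlg1-2 2 h replicate 1), 240 and 324 for gpb1-2 (240 without Tak-1 0 h replicate 1), 17 and 136 for xlg1-2 against gpb1-2 (70 and 23 without gpb1-2 replicate 1 and 3, 17 and 20 without xlg1-2 replicate 2 and 3) and 28 and 237 for xlg1-2 (53, 237 and 49 without Tak-1 replicate 1, 2 and 3, 84 and 28 without xlg1-2 replicate 1 and 2). In the WRKY table they were 2084 and 3716 for Tak-1 at 2 h (2217 without 0 h replicate 2, 2371 and 2084 without 2 h replicate 1 and 2), 3322 and 4453 at 24 h (3322 without 0 h replicate 2), 1 and 2 for wrky12, 6 and 64 for wrky6 (64 without wrky6 replicate 1), and 0 and 2 for the wrky6 salt response (2 without wrky6 0 h replicate 1). In rice they were 0 and 0 for NB at 2 h, 0 and 2674 at 24 h (2674 without 24 h replicate 3) and 2 and 8 for xlg1,4.

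What depth limits was not tested on its own. Recovery of genes changed 1.5-fold in simulated data was 56.7% for Marchantia gpa1-2 at 0 h (median 10.5 M counts), 53.7% for Arabidopsis gpa1-3 at 0 h (29.7 M) and 7.5% for rice xlg1,4 at 0 h (17.0 M). The simulations took the spread between libraries from the groups as labelled. In rice these groups held the libraries in doubt, so the 3 values do not show how recovery depends on depth.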

Other observations

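All tests and genes here were chosen only after the values were seen.

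Seed storage transcripts stood out in Arabidopsis. CRA1 was at 10 CPM or more in 13 of 44 libraries, and CRU3 in 12 of those. In gpa1-3 at 0 h all 3 libraries had 52 to 116 CPM of CRA1, against 0.0281 to 0.185 CPM in Col-0 at 0 h. At 2 h the 3 gpa1-3 libraries had 0.168 to 0.85 CPM. In xlg1,2,3, 2 of 3 libraries passed 10 CPM at 0 h (45.1 and 25.3) and 2 of 3 at 2 h (64.1 and 31.7). In agb1-2, 1 library did so at 0 h (10.1), at 2 h (15.2) and at 24 h (32). The others were gpa1-3 24 h replicate 2 (293), gpa1-3 tunicamycin replicate 1 (82.7) and Col-0 24 h replicate 1 (55.4).

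In Col-0 HSP70 was at 987 ± 266 CPM at 0 h, 229 ± 55.5 at NaCl 2 h, 895 ± 898 at 24 h and 35.7 ± 4.5 after tunicamycin, and JAZ10 at 80.2 ± 5.26, 12.9 ± 9.01, 10.2 ± 1.47 and 1.8 ± 0.589 CPM.

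Some genes had a gap of more than 10-fold between all mutant and all wild-type libraries over every time, with at least 10 CPM in the higher genotype. HEI10 was at 28.7 to 40.8 CPM in xlg1,2,3 libraries and 0.844 to 1.96 CPM in Col-0. AT5G35935 was at 12.7 to 23.1 CPM in gpa1-3 and 15.5 to 24.5 CPM in agb1-2, against 0.213 to 0.717 CPM in Col-0. In Marchantia gpa1-2, 2 loci were higher and 4 lower at every time, among them Mapoly0001s0008 at 30 to 55.3 CPM against 0 to 0.171 in Tak-1 and MapolyY_A0047 at 0 to 0.137 against 12.9 to 20.3 CPM. By this criterion there were 0 loci in gpb1-2, xlg1-2 and wrky6. In the WRKY table, Mp7g01940 was at 10400 to 12600 CPM in wrky12 and 420 to 597 CPM in Tak-1.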
